A study of Homo sapiens with 100 samples.

How the data were processed

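The deposited table held values of 100 Affymetrix arrays. The authors named RMA as the processing, which gives log2 values, but did not state the scale. It was taken as log2 from the range of 2.18 to 14.97 and array medians between 5.90 and 6.10. RNA had been amplified and labelled with biotin by a 3' in vitro transcription kit from 100 ng of total leukocyte RNA. The authors also named limma, and gave a version for neither tool. Values of the table and of the series record were equal in all 96 columns that could be matched by name (0 values differed), and each of the other 4 columns equalled an array of its group. These are at 6 hr, 1 per dose, and carry in the table a replicate number that no label of their group has, where the labels have number 5. For that reason 6 hr was paired with 1 hr through numbers 1 to 4 only. Within 6 hr the arrays labelled 5 were paired as the other numbers were. The table held 49395 probe sets that are not ERCC controls, of which 44994 had 1 gene symbol and 1832 several, 2473 had none and were not controls, and the rest were Affymetrix controls without a symbol. From these, 103 probe sets of XIST, TSIX and Y-linked genes were left out of every test. Probe sets with several symbols or none were left out as well. The probe set with the highest mean stood for a gene (18106 genes, 11722 of them with more than 1 probe set). Genes above a log2 value of 5 on at least 5 arrays were tested, 14015 in all.

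The design text says that the same volunteers were measured at every dose. Sample labels give replicate numbers but do not say that a number is a volunteer, so the numbers were checked in the values. After removal of the group means, arrays with the same number at 2 doses correlated at no less than 0.602 at 1 hr (60 pairs, median 0.787, other pairs -0.076), 0.657 at 2 hr (60 pairs, median 0.787, other pairs -0.064) and 0.699 at 6 hr (30 pairs, median 0.816, other pairs -0.175). Across times the lowest value was 0.285 between 1 and 2 hr (160 pairs, median 0.66) and 0.204 between 1 and 6 hr (numbers 1 to 4, 64 pairs, median 0.388). Other pairs reached 0.315 and 0.182 there, so the ranges overlapped between 1 and 2 hr and nearly met between 1 and 6 hr. The numbers therefore pair the arrays, clearly within a time and less clearly across times. Results with the replicate number as a block are printed beside each result whose call or count they moved.

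Tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Each comparison was a contrast in 1 limma model of 12 group means (lmFit and eBayes, 88 residual degrees of freedom), with Benjamini-Hochberg adjustment over the 14015 genes and a threshold of 0.05. For dose comparisons and interactions the fit with the replicate block added a coefficient for each replicate number within each time (66 residual degrees of freedom). For a comparison of times the arrays of those 2 times alone were fitted, with the number as the block across them. Both fits used limma, and "in limma" below means the fit of group means without the block. Fold and SE come from the fit without the block. A p-value states how often a difference as large would arise by chance if the groups did not differ, and the number of arrays limits the precision, most at 6 hr. Comparisons were each dose against 0 Gy at its time, 1.5 against 0.30 Gy, 2 and 6 hr against 1 hr at 0 Gy, and the change of the 1.5 Gy effect with time.

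Named genes were, for 1.5 Gy against 0 Gy, up to 12 that rose and 8 that fell with the largest absolute log2 change among genes past the threshold. The quotas were 5 and 5 for the other dose comparisons and the interactions and 10 and 10 for the times, and unfilled places were filled from the fit with the block. In every dose comparison CDKN1A, MDM2, DDB2, GADD45A, XPC, PHPT1, AEN, BBC3 and PCNA were named whether or not they passed. FDXR, the tenth, had no tested probe set and was not analysed here. Members of lists were named by the smallest p.

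The 22 gene lists were tested with camera on the limma model with an inter-gene correlation of 0.01, adjusted over all 352 list tests. They were p53 targets (38 tested genes), double-strand break repair (19), NF-kB inflammatory genes (27), immediate early genes (27), interferon response (28), heat shock (17), hypoxia and glycolysis (26), unfolded protein and integrated stress response (18), oxidative stress response (18), proliferation (22), BCL2 family and death receptors (22), cytosolic ribosomal proteins (28), circadian clock (14), glucocorticoid response (13), and markers of T cells (13), NK cells (13), B cells (14), monocytes (13), neutrophils (15), eosinophils and basophils (12), erythroid cells (9) and platelets (14). Members that another list also holds numbered 6 in the p53 list, 5 in the BCL2 list, 4 in the glucocorticoid list and 1 each in the immediate early, hypoxia, unfolded protein, oxidative stress, circadian, monocyte and neutrophil lists. Alternatives were an estimated correlation for each list, the block, no filter on dim genes and lists without shared members.

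Alternatives for genes were the replicate block, no filter, a stricter filter (log2 above 6, 11511 genes), every probe set on its own (35523), arrays centred on their medians, a fit of only the groups compared, a trended and robust prior, and leaving out each 6 hr array in turn. Added after the data were seen were fits without the array of lowest mean correlation in each 1 and 2 hr group, with and without the block, and the list test with both the block and an estimated correlation. The 3' minus 5' signal of the GAPDH and ACTB control probe sets was compared by permutation, exact where all splits could be listed. A self-test used simulated arrays in which genes varied independently of each other. Planted genes numbered 50 each at log2 changes of 0.25, 0.5, 1 and 2. The model found 15, 38, 49 and 50 of them at 1 hr and 4, 24, 47 and 49 at 6 hr with 0 false calls in either. With the block it found 41, 48, 50 and 50 and 33, 44, 50 and 50, with 12 and 14 false calls. The planted list was found each time and 0 of 50 random lists passed. Because the simulated genes were independent, these results do not give error rates for the real arrays, where genes can vary together.

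The work used R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9.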

Results

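Blood of 10 volunteers was irradiated in the tube with 0, 0.15, 0.30 or 1.5 Gy of gamma rays and kept warm for 1, 2 or 6 hr before the red cells were lysed and the leukocyte RNA was put on Affymetrix arrays. The 100 arrays formed 12 groups of dose and time, with 10 arrays per group at 1 hr and at 2 hr and 5 per group at 6 hr. Deposited log2 values ran from 2.18 to 14.97, and the median of an array lay between 5.90 and 6.10. The correlation between 2 arrays ran from 0.9501 to 0.9975. The comparisons addressed which transcripts respond within hours to low doses, and 14015 genes were tested. FDXR, a radiation response gene picked beforehand, had no tested probe set and was not analysed here.

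At 1 hr, 1.5 Gy was compared with 0 Gy to find the first transcripts to respond. PLK2, which encodes a polo-like kinase, rose from a mean log2 value of 5.19 to 6.73, a difference of 1.53 ± 0.14 (SE, n = 10 per group, 2.89-fold). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.37 ± 0.15 and AEN, a nuclease gene under p53 control, by 1.21 ± 0.12, each in 10 of 10 pairs of arrays with the same replicate number. The transcription factor gene JUN rose by 1.14 ± 0.22 in 9 of 10 pairs, and the lymphocyte activation genes CD69 and CD83 rose by 1.07 ± 0.22 and 0.95 ± 0.20 in 10 of 10. GADD45A, a growth arrest gene, rose by 0.72 ± 0.14 and PCNA, the sliding clamp of DNA polymerases, by 0.57 ± 0.09. Adjusted p was 3.32e-14 for PLK2, 1.6e-10 for CDKN1A, 4.41e-12 for AEN and 0.00226 for JUN. IER5, the signalling adaptor gene TRAF4, TRIAP1, an inhibitor of apoptosis under p53 control, and RND1 rose by 0.67, 0.61, 0.57 and 0.51. C7orf25 fell by 0.55 ± 0.13 (adjusted p = 0.0362) and the golgin gene GOLGA5 fell by 0.32 ± 0.07 (adjusted p = 0.0197), each in 10 of 10 pairs.

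With those named above, 17 of the 14015 genes passed after 1.5 Gy at 1 hr, 15 that rose and 2 that fell. With the replicate block 1701 genes were past the threshold, 529 that rose and 1172 that fell. When the array of lowest correlation in each 1 and 2 hr group was left out, 540 rose and 797 fell with the block. The excess of genes that fell thus depends in part on those arrays. In the fit with the block, the genes that fell most included NFE2, a transcription factor of the erythroid and megakaryocyte lineages, by 0.61 (adjusted p = 2.32e-07), and KCNJ2, a potassium channel gene, by 0.59 (adjusted p = 1.46e-05). HHEX, MYCL, ING1 and ADAMTS1 also fell in that fit, by 0.56, 0.56, 0.53 and 0.52. The median absolute log2 change of its 1701 genes was 0.168, and 18 of them changed by over 1.5-fold. BBC3, an apoptosis gene (0.48 ± 0.14, adjusted p = 0.322), passed with the block (adjusted p = 1.07e-05), as did MDM2, a ligase gene that restrains p53 (0.23 ± 0.12, adjusted p = 0.0239 with the block). DDB2, XPC and PHPT1 did not pass in either fit, with differences of 0.10, -0.003 and -0.002. Fitting only the groups compared left 4 genes, and JUN, CD69, CD83, GADD45A, IER5, TRAF4, TRIAP1, PCNA, C7orf25 and GOLGA5 lost their calls (adjusted p from 0.0752 to 0.335). C7orf25 did not pass without the array of lowest correlation in each group (adjusted p = 0.198), and GOLGA5 did not pass with centred arrays (adjusted p = 0.142).

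Among the gene lists, 8 of 38 p53 targets rose at 1 hr after 1.5 Gy, 12 adjusted over the list alone, with a median difference of 0.12 (adjusted p = 7.54e-22 for the list). Of the 27 immediate early genes, which respond to stimuli without new protein synthesis, JUN alone rose, 2 adjusted over the list alone, and the list rose (adjusted p = 0.00127, adjusted p = 0.934 with an estimated correlation). The 27 NF-kB inflammatory genes also rose as a list (median 0.18, adjusted p = 0.000216, adjusted p = 0.942 with an estimated correlation), with CD83 past the threshold over all genes and adjusted over the list alone. In the fit with the block, MYC rose by 0.58 (adjusted p = 2.92e-08) and the cytokine gene TNF by 0.58 (adjusted p = 6.58e-08). Markers of other cell types moved with them. The 13 NK cell markers fell as a list (median -0.22, adjusted p = 0.00275, adjusted p = 0.999 with an estimated correlation). Singly 0 of them passed in limma and 7 with the block, such as GZMB, a cytotoxic granule protease (-0.31, adjusted p = 0.000596 with the block). The 9 erythroid markers rose as a list (median 0.32, adjusted p = 0.013, adjusted p = 0.999 with an estimated correlation), with SELENBP1 at 0.35 (adjusted p = 0.0129 with the block).

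At 1 hr the low doses were compared with 0 Gy to ask how little radiation gives a response. PLK2, AEN and CDKN1A rose after both low doses, each in 10 of 10 pairs. After 0.15 Gy they rose by 0.95 ± 0.14, 0.83 ± 0.12 and 0.75 ± 0.15 (n = 10 per group, adjusted p = 8.05e-06, 8.05e-06 and 0.0168). After 0.30 Gy they rose by 0.96 ± 0.14, 0.99 ± 0.12 and 0.98 ± 0.15 (adjusted p = 5.66e-06, 4.66e-08 and 2.92e-05). No other gene passed without the block, so each dose gave 3 genes, 0 of them lower in limma, with 221 and 373 genes at an unadjusted p under 0.05. CDKN1A after 0.15 Gy lost its call when only the groups compared were fitted (adjusted p = 0.286).

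With the replicate block 413 genes passed after 0.15 Gy at 1 hr, 104 that rose and 309 that fell, and 1006 after 0.30 Gy, 406 that rose and 600 that fell. In that fit JUN rose by 0.59 after 0.15 Gy (adjusted p = 4.97e-05) and PMAIP1, which encodes the apoptosis protein NOXA, by 0.57 (adjusted p = 2.7e-11). The monocyte chemokine genes CCL7 and CCL2 rose by 1.00 and 0.87 after 0.30 Gy (adjusted p = 0.00806 and 0.00692 with the block, in 7 and 9 of 10 pairs). KCNJ2, NFE2 and SOCS3, a suppressor of cytokine signalling, fell by 0.76, 0.62 and 0.60 after 0.15 Gy and by 0.71, 0.56 and 0.47 after 0.30 Gy with the block. The stress chaperone gene HSPA6 and ING1 fell by 0.45 and 0.45 after 0.15 Gy, and MYCL and RNF144B, a ubiquitin ligase gene, fell by 0.58 and 0.47 after 0.30 Gy. Of the radiation response genes, GADD45A (0.32 and 0.41) and PCNA (0.31 and 0.34) passed at both doses with the block and not without it, while MDM2, DDB2, XPC, PHPT1 and BBC3 did not pass at either dose (-0.03 to 0.17). Median absolute changes in the fit with the block were 0.183 and 0.173, and 7 and 15 genes changed by over 1.5-fold.

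The p53 target list rose at 1 hr after 0.15 Gy (adjusted p = 2.45e-09, median 0.042) and after 0.30 Gy (adjusted p = 7.91e-12, median 0.058). At each dose 3 of 38 members passed, and 7 and 11 did adjusted over the list alone. With both the block and an estimated correlation these lists did not pass (adjusted p = 0.138 and 0.111). After 0.30 Gy the immediate early genes (adjusted p = 5.81e-05, adjusted p = 0.581 with an estimated correlation) and the NF-kB genes (adjusted p = 8.47e-05, adjusted p = 0.942 with an estimated correlation) rose as lists. Singly 0 members passed in limma. Adjusted over the list alone, 1 immediate early gene and 0 NF-kB genes passed, and with the block 10 and 6 did, such as FOSB (0.67, adjusted p = 2.7e-05) and TNF (0.42, adjusted p = 0.000111). The NK cell markers fell as a list after 0.15 Gy (median -0.13, adjusted p = 0.0237) and 0.30 Gy (median -0.17, adjusted p = 0.00954), each with adjusted p = 0.999 with an estimated correlation. With the block, the NF-kB genes and immediate early genes also passed as lists after 0.15 Gy (adjusted p = 0.00218 and 0.00101), as did the monocyte markers (adjusted p = 0.0161), all higher. None of these 3 passed with the block and an estimated correlation (adjusted p = 0.582, 0.343 and 0.541). The unfolded protein and integrated stress response genes rose as a list with the block after all 3 doses at 1 hr (adjusted p = 0.0275, 0.0334 and 0.00781), and with an estimated correlation as well they did not pass (adjusted p = 0.139, 0.158 and 0.0677). TRIB3, a pseudokinase of that response, was among them (0.51 after 0.30 Gy, adjusted p = 5.86e-08 with the block).

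**Figure D1:**
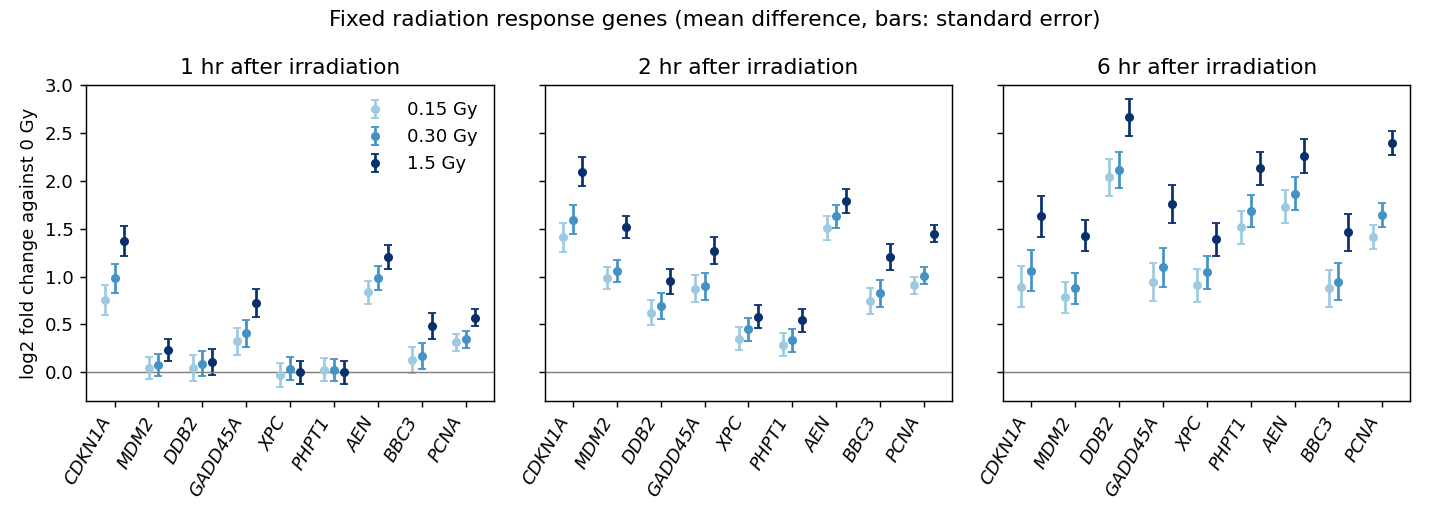
Log2 difference from 0 Gy at the same time (vertical axis) for the radiation response genes (horizontal axis), in a panel for each time and a shade of blue for each dose, with bars of 1 SE from limma (n = 10 per group at 1 and 2 hr, 5 at 6 hr). CDKN1A was already 1.37 above 0 Gy at 1 hr after 1.5 Gy, whereas DDB2 went from 0.10 at 1 hr to 2.66 at 6 hr.

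At 2 hr after 1.5 Gy the p53 targets CDKN1A and PLK2 rose by 2.10 ± 0.15 and 2.07 ± 0.14 (n = 10 per group, 4.28-fold and 4.19-fold, adjusted p = 1.8e-20 and 2.46e-22). The mean log2 value of CDKN1A went from 9.71 to 11.81. AEN, TRIAP1, MDM2 and PCNA rose by 1.79, 1.52, 1.51 and 1.45, and the ribosomal protein-like gene RPS27L by 1.32 ± 0.09 (adjusted p = 1.28e-22). The B cell co-stimulatory receptor gene CD40 rose by 1.89 ± 0.28 (adjusted p = 8.49e-07) and CD83 by 1.63 ± 0.20 (adjusted p = 1.43e-09). The TNF family ligand gene CD70 rose by 1.27 ± 0.18 (adjusted p = 1.6e-07) and the cytokine subunit gene EBI3 by 1.28 ± 0.14 (adjusted p = 5.89e-12). LINC00158, a long noncoding RNA, rose by 1.33 ± 0.13 (adjusted p = 4.51e-14), and all of these genes were higher in 10 of 10 pairs. Among the genes that fell, FAM111B, a protease gene, fell by 1.02 ± 0.24 (adjusted p = 0.00893). The B cell adaptor gene BLNK fell by 0.88 ± 0.21 (adjusted p = 0.00856) and VPREB3, a gene of the B cell precursor receptor, by 0.71 ± 0.19 (adjusted p = 0.0446).

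Without the block 134 genes passed at 2 hr after 1.5 Gy, 122 that rose and 12 that fell, and with it 3301, 2000 that rose and 1301 that fell, with a median absolute change of 0.177 and 83 genes over 1.5-fold. ZNF860 fell by 1.11 ± 0.27 (adjusted p = 0.0137), PRICKLE1, a planar polarity gene, fell by 0.65 ± 0.10 (adjusted p = 2.61e-06), and the immunoglobulin segment IGHV5-78, CCNG2, an atypical cyclin gene, and HHEX fell by 0.94, 0.62 and 0.52. The other radiation response genes all rose, GADD45A by 1.27, BBC3 by 1.21, DDB2 by 0.95, XPC by 0.58 and PHPT1 by 0.54, in 10 of 10 pairs. Fitting only the groups compared gave 89 genes, and IGHV5-78, VPREB3, CCNG2 and HHEX lost their calls there (adjusted p = 0.129, 0.0665, 0.0598 and 0.234) and with no filter on dim genes (adjusted p = 0.0557, 0.055, 0.0519 and 0.0557).

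Of the 38 p53 targets 21 rose at 2 hr after 1.5 Gy (median 0.54, adjusted p = 1.45e-81), and adjusted over the list alone 24 rose and 1 fell. In the BCL2 family and death receptor list 3 of 22 members rose, 4 adjusted over the list alone (list adjusted p = 1.79e-05). These were BAX (0.68 ± 0.06) and BBC3, which promote apoptosis, and the death receptor gene TNFRSF10B (0.53 ± 0.12), and without the 5 members it shares with other lists the list did not pass (adjusted p = 0.658). The NF-kB genes rose as a list (median 0.19, adjusted p = 0.000216, adjusted p = 0.942 with an estimated correlation) with CD83 past the threshold, 2 genes adjusted over the list alone, and NFKB1 at 0.44 (adjusted p = 8.24e-12 with the block). The 17 heat shock genes rose as a list (median 0.26, adjusted p = 0.00348, adjusted p = 0.999 with an estimated correlation). Singly 0 members passed in limma, and 13 rose with the block, such as the chaperone genes CHORDC1 (0.36) and DNAJA1 (0.26). Of the 14 B cell markers BLNK and VPREB3 fell, and the list fell (median -0.19, adjusted p = 0.0218, adjusted p = 0.999 with an estimated correlation). Adjusted over the list alone 1 B cell marker rose and 4 fell, and with the block TCL1A fell by 1.20 (adjusted p = 5.5e-18) while MS4A1, which encodes CD20, rose by 0.84 (adjusted p = 1.56e-18). The 15 neutrophil markers fell as a list (median -0.12, adjusted p = 0.0218, adjusted p = 0.942 with an estimated correlation). Singly 0 of them fell in limma and 8 with the block, such as the interleukin 8 receptor genes CXCR1 (-0.41) and CXCR2 (-0.33). Without shared members the neutrophil list did not pass (adjusted p = 0.0701). The eosinophil and basophil markers fell as a list with the block (adjusted p = 0.0434), and not with an estimated correlation as well (adjusted p = 0.359). The heat shock and NF-kB lists also rose from 1 to 2 hr at 0 Gy, and the neutrophil list fell there with the block. Whether irradiated tubes stood longer than the 0 Gy tubes at 2 hr was not tested.

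At 2 hr after the low doses AEN, CDKN1A, PLK2 and TRIAP1 rose by 1.51 ± 0.12, 1.41 ± 0.15, 1.41 ± 0.14 and 1.12 ± 0.12 at 0.15 Gy (n = 10 per group). At 0.30 Gy they rose by 1.63 ± 0.12, 1.60 ± 0.15, 1.47 ± 0.14 and 1.25 ± 0.12. Each was higher in 10 of 10 pairs. AEN, whose mean log2 value at 0 Gy was 7.14, thus rose 2.84-fold at 0.15 Gy (adjusted p = 7.51e-17) and 3.10-fold at 0.30 Gy (adjusted p = 7.43e-19). MDM2 rose by 0.99 and 1.06, PCNA by 0.91 and 1.01, GADD45A by 0.87 and 0.90, BBC3 by 0.74 and 0.82, and DDB2 by 0.62 and 0.69. RPS27L rose by 1.11 ± 0.09 at 0.30 Gy (adjusted p = 4.33e-18). The nucleotide excision repair gene XPC (0.35 and 0.45) and the phosphatase gene PHPT1 (0.28 and 0.33) passed with the block and not without it. XPC after 0.30 Gy also passed without the block when the array of lowest correlation in each group was left out (0.49, adjusted p = 0.0281), and DDB2 after 0.15 Gy lost its call when only the groups compared were fitted (adjusted p = 0.0657).

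These comparisons at 2 hr called 15 genes after 0.15 Gy and 20 after 0.30 Gy, all of them higher, and with the block 614 (291 that rose, 323 that fell) and 1701 (1048 that rose, 653 that fell). In limma without the block 0 genes fell, with 189 and 416 at an unadjusted p under 0.05. Genes that fell in the fit with the block were FAM111B, by 0.54 and 0.62 at the 2 doses, and RNF24, by 0.50 and 0.58. TGFA, a growth factor gene, MAK, a kinase gene, and TCL1A fell by 0.48, 0.45 and 0.44 after 0.15 Gy, and ZNF860, NFE2 and ANKRD34B fell by 0.62, 0.60 and 0.52 after 0.30 Gy. Median absolute changes with the block were 0.173 and 0.168, and 16 and 29 genes changed by over 1.5-fold.

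The p53 targets rose at 2 hr after 0.15 Gy (14 of 38, 22 adjusted over the list alone, median 0.34, adjusted p = 2.83e-113) and after 0.30 Gy (15 of 38, 22 adjusted over the list alone, median 0.39, adjusted p = 1.01e-93). BAX and BBC3 rose in the BCL2 family and death receptor list at both doses, 3 members adjusted over the list alone, and the list rose (adjusted p = 1.51e-07 and 7.52e-06), although not without shared members (adjusted p = 0.267 and 0.576). The NF-kB genes rose as a list at both doses (adjusted p = 0.0108 and 0.00108, each adjusted p = 0.999 with an estimated correlation). At 0.15 Gy 0 of them passed singly in limma and 1 adjusted over the list alone, and at 0.30 Gy CD83 did in both (1.01 ± 0.20, adjusted p = 0.00204). After 0.30 Gy the heat shock genes rose (adjusted p = 0.0257, adjusted p = 0.999 with an estimated correlation) and the neutrophil markers fell (median -0.14, adjusted p = 0.012, adjusted p = 0.942 with an estimated correlation). No member of those 2 lists passed singly in limma, and with the block DNAJA1 rose by 0.17 and CXCR1 fell by 0.36. After 0.15 Gy, with the block, the neutrophil (adjusted p = 0.000856) and T cell markers (adjusted p = 0.00255) fell and the monocyte markers rose (adjusted p = 0.031) as lists. None of the 3 passed with an estimated correlation as well (adjusted p = 0.3, 0.472 and 0.589). The NF-kB, heat shock and neutrophil lists moved the same ways from 1 to 2 hr at 0 Gy, the neutrophil list with the block.

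At 6 hr after 1.5 Gy the DNA damage recognition gene DDB2 rose from a mean log2 value of 7.32 to 9.98, by 2.66 ± 0.19 (n = 5 per group, 6.34-fold, adjusted p = 4.9e-21). TNFSF4, the OX40 ligand gene, rose by 2.64 ± 0.20 from a mean of 5.06 (6.21-fold, adjusted p = 4.61e-19). PCNA rose by 2.40 ± 0.13, AEN by 2.26 ± 0.17, TRIAP1 by 2.16 ± 0.17 and PHPT1 by 2.13 ± 0.17. POLH, a polymerase that copies past damaged bases, and ASCC3, a helicase of alkylation repair, rose by 1.91 ± 0.17 and 1.80 ± 0.14. The actin gene ACTA2, GADD45A, RPS27L and EBI3 rose by 1.78, 1.76, 1.76 and 1.70. The G protein subunit gene GNG7 fell by 1.44 ± 0.28 (adjusted p = 0.000597) and TBXAS1, the thromboxane synthase gene, fell by 0.59 ± 0.11 (adjusted p = 0.000304), and each named change was seen in 5 of 5 pairs. TBXAS1 lost its call when only the groups compared were fitted (adjusted p = 0.775).

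There were 78 genes past the threshold at 6 hr after 1.5 Gy, 76 that rose and 2 that fell, and 1992 with the block, 1071 that rose and 921 that fell, with a median absolute change of 0.24 and 125 genes over 1.5-fold. CDKN1A, BBC3, MDM2 and XPC rose by 1.63, 1.46, 1.43 and 1.39 (adjusted p = 2.33e-08, 2.78e-08, 8.58e-11 and 2.61e-09). In the fit with the block DSP, the desmoplakin gene, fell by 1.25 (adjusted p = 1.36e-09), NIBAN3, a B cell gene, by 1.18 (adjusted p = 2.49e-12) and the tetraspanin gene TSPAN13 by 1.04 (adjusted p = 1.35e-11). FAM111B and VPREB3 fell by 0.96 and 0.92 in that fit. HSPA1B fell by 0.97 with the block (adjusted p = 0.00471, 4 of 5 pairs), and its probe set cannot be told from the near-identical gene HSPA1A.

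Of the p53 targets 24 of 38 rose at 6 hr after 1.5 Gy (median 1.13, adjusted p = 5.25e-173), and adjusted over the list alone 28 rose and 1 fell. BAX (1.63 ± 0.09), BBC3 and TNFRSF10B (0.84 ± 0.17) rose in the BCL2 family and death receptor list, 4 members adjusted over the list alone, and the list rose (adjusted p = 2.52e-07), although not without shared members (adjusted p = 0.93). The heat shock genes fell as a list (median -0.28, adjusted p = 0.000495, adjusted p = 0.942 with an estimated correlation). So did the 26 hypoxia and glycolysis genes (median -0.11, adjusted p = 0.000681, adjusted p = 0.934 with an estimated correlation). With the block, the chaperone gene DNAJB1 (-0.76), the histone demethylase gene KDM3A (-0.36) and the pyruvate dehydrogenase kinase gene PDK1 (-0.44) were among 10 heat shock and 12 hypoxia genes that fell. The neutrophil markers fell as a list (median -0.33, adjusted p = 2.88e-05, adjusted p = 0.332 with an estimated correlation), with 11 of 15 past the threshold with the block, such as VNN2 (-0.72) and MME, a surface peptidase (-0.66). In these 3 lists 0 members passed singly in limma over all genes or adjusted over the list alone. As lists with the block, the B cell (adjusted p = 0.0126, although MS4A1 rose by 0.54, adjusted p = 2.77e-06), eosinophil and basophil (adjusted p = 0.0313) and circadian clock lists (adjusted p = 0.0438) fell, and the ribosomal protein (adjusted p = 0.00304) and NF-kB lists (adjusted p = 0.0336) rose. With an estimated correlation as well these 5 did not pass (adjusted p = 0.509, 0.333, 0.331, 0.646 and 0.776).

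At 6 hr after the low doses DDB2, AEN, PHPT1, TRIAP1 and PCNA were the genes that rose most. They rose by 2.04 ± 0.19, 1.73 ± 0.17, 1.51 ± 0.17, 1.40 ± 0.17 and 1.42 ± 0.13 after 0.15 Gy (n = 5 per group). After 0.30 Gy they rose by 2.12 ± 0.19, 1.87 ± 0.17, 1.69 ± 0.17, 1.66 ± 0.17 and 1.65 ± 0.13, and all were higher in 5 of 5 pairs. DDB2 thus rose 4.10-fold at the lowest dose (adjusted p = 2.39e-14) and 4.33-fold at the middle dose (adjusted p = 3.23e-15). GADD45A rose by 0.94 and 1.10, XPC by 0.91 and 1.04, BBC3 by 0.88 and 0.94, and MDM2 by 0.78 and 0.88. CDKN1A rose by 1.06 after 0.30 Gy (adjusted p = 0.00237), and after 0.15 Gy it just missed the threshold (0.89 ± 0.22, adjusted p = 0.0517). It passed there with the block (adjusted p = 2.85e-05), with the stricter filter (adjusted p = 0.0433) and without either of 2 arrays of 0 Gy (adjusted p = 0.0187 and 0.0165).

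In all 21 genes rose at 6 hr after 0.15 Gy and 33 after 0.30 Gy, with 0 genes lower in limma and 148 and 343 at an unadjusted p under 0.05. The block gave 159 (114 that rose, 45 that fell) and 1109 (756 that rose, 353 that fell), with median absolute changes of 0.328 and 0.226 and 31 and 51 genes over 1.5-fold. In that fit the growth regulator gene MYC, the arginase gene ARG1, the secreted protein gene PROK2, GNG7 and TSPAN13 fell by 0.59, 0.47, 0.45, 0.44 and 0.41 after 0.15 Gy. DSP, GNG7, NSUN7, ASAP1-IT2 and MME fell by 1.09, 0.64, 0.62, 0.57 and 0.55 after 0.30 Gy. Fitting only the groups compared left 10 genes after 0.15 Gy, where TRIAP1, MDM2, XPC and BBC3 lost their calls (adjusted p = 0.055, 1, 0.0621 and 0.267), and after 0.30 Gy CDKN1A, MDM2 and BBC3 did (adjusted p = 0.653, 0.413 and 0.0544). After 0.15 Gy MDM2, GADD45A and BBC3 each missed the threshold without some single arrays, with adjusted p up to 0.16, 0.0726 and 0.185. CDKN1A also missed it after 0.30 Gy without 1 of the 0 Gy arrays (adjusted p = 0.126).

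The p53 targets rose at 6 hr after 0.15 Gy (17 of 38, 23 adjusted over the list alone, median 0.71, adjusted p = 1.17e-171) and 0.30 Gy (20 of 38, 24 adjusted over the list alone, median 0.82, adjusted p = 1.49e-132). BAX rose by 1.26 ± 0.09 and 1.39 ± 0.09. With BBC3 it made 2 members of the BCL2 family and death receptor list past the threshold at each dose, 3 adjusted over the list alone. The list rose (adjusted p = 2.45e-09 and 1.03e-05), although not without shared members (adjusted p = 0.591 and 0.952). The heat shock genes fell as a list after 0.15 Gy (median -0.22, adjusted p = 0.00214, adjusted p = 0.999 with an estimated correlation). Singly 0 members passed in limma, with HSPA1L at -0.33 (adjusted p = 0.00303 with the block). The neutrophil markers fell after 0.30 Gy (median -0.20, adjusted p = 0.00303, adjusted p = 0.757 with an estimated correlation), 0 singly in limma and 9 with the block, such as MME and VNN2 (-0.45). With the block, the 28 interferon response genes rose as a list after 0.15 Gy (adjusted p = 3.02e-07) and 0.30 Gy (adjusted p = 0.00103), and with an estimated correlation as well they did not pass (adjusted p = 0.0832 and 0.333). Among them were MX1 at 0.24 after 0.15 Gy (adjusted p = 0.0294 with the block) and EPSTI1 at 0.30 after 0.30 Gy (adjusted p = 0.000227 with the block). Also with the block, the NF-kB genes rose (adjusted p = 0.003) and the T cell (adjusted p = 0.0328) and neutrophil markers (adjusted p = 5.07e-07) fell as lists after 0.15 Gy, none of them with an estimated correlation as well (adjusted p = 0.601, 0.656 and 0.0818). After 0.30 Gy the stress response genes (adjusted p = 0.0249) and monocyte markers (adjusted p = 0.00304) rose and the heat shock genes fell (adjusted p = 0.00603) as lists with the block. With an estimated correlation as well these 3 did not pass (adjusted p = 0.133, 0.43 and 0.567).

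**Figure D2:**
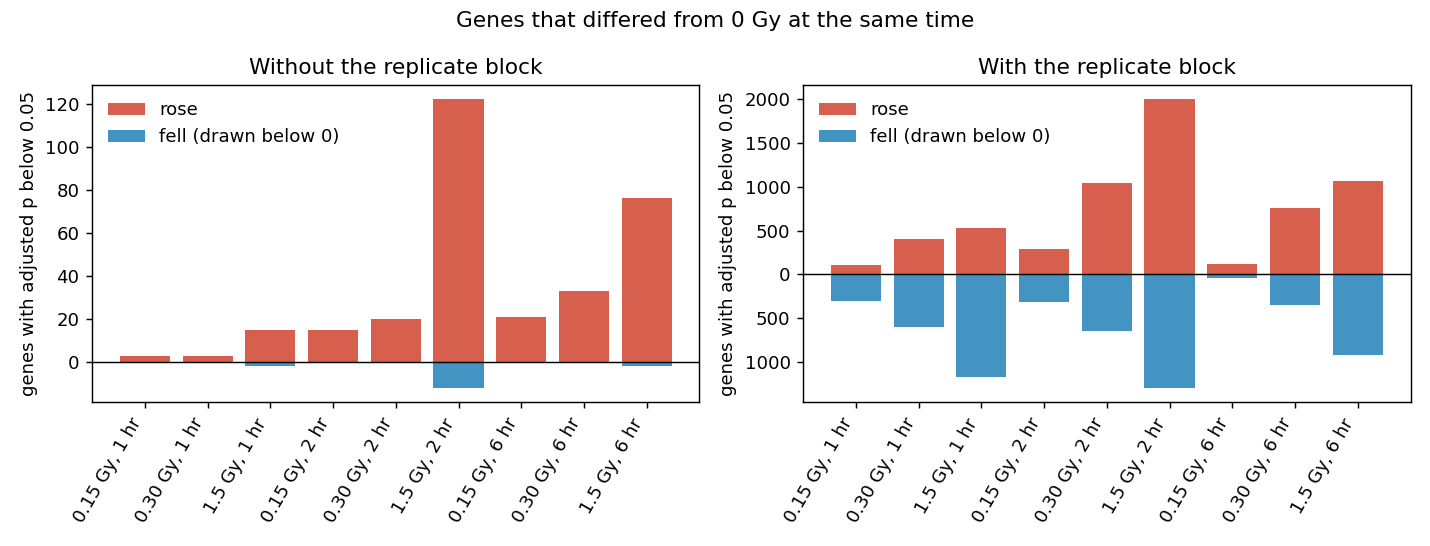
Genes with adjusted p below 0.05 (vertical axis, counts of genes that fell drawn below 0, another scale in each panel) for each dose and time (horizontal axis), without the replicate block and with it. Without the block 134 genes passed at 2 hr after 1.5 Gy, and with it 3301.

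The highest and the middle dose were compared to ask whether the response grew with dose. At 2 hr LINC00158 was higher at 1.5 Gy than at 0.30 Gy by 1.12 ± 0.13 (n = 10 per group, adjusted p = 1.07e-09) and EBI3 by 0.89 ± 0.14 (adjusted p = 2.42e-05). The co-stimulatory ligand gene CD80, the semaphorin gene SEMA7A and IL2RA, the interleukin 2 receptor alpha chain gene, were higher by 0.73, 0.71 and 0.67, and all 5 were higher in 10 of 10 pairs. At 6 hr EBI3, TNFSF4, PCNA and VWCE were higher at 1.5 Gy by 1.29 ± 0.19, 1.28 ± 0.20, 0.75 ± 0.13 and 0.65 ± 0.12 (n = 5 per group, adjusted p = 2.42e-05, 7.36e-05, 0.000218 and 0.00252), in 5 of 5 pairs. PCNA was also higher at 2 hr (0.44 ± 0.09, adjusted p = 0.00695).

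At 2 hr 16 genes passed between 1.5 and 0.30 Gy, all higher at 1.5 Gy, and 253 with the block (172 higher, 81 lower). At 6 hr 4 passed and 182 with the block (76 higher, 106 lower). At 1 hr limma called 0 genes, with 205 at an unadjusted p under 0.05, and with the block 5 genes were higher, PLK2 (0.57), CD69 (0.48), CD40 (0.47), TRAF4 (0.37) and POLR3D (0.23). With the block the B cell genes TCL1A, IGHV5-78, BLNK and POU2AF1 were lower at 2 hr by -0.74, -0.66, -0.53 and -0.52, as was ZNF860 (-0.48), while MS4A1 was higher (0.39, adjusted p = 9.11e-06). At 6 hr CD80 was higher (0.85) and NIBAN3, GNG7, FAM111B, IGHV5-78 and the sodium channel gene SCN3A were lower (-0.80, -0.79, -0.68, -0.66 and -0.65) with the block. Of the other radiation response genes, CDKN1A, MDM2, GADD45A, PHPT1 and BBC3 passed at 2 hr with the block and not without it (0.50, 0.45, 0.37, 0.21 and 0.38), where DDB2, XPC and AEN did not pass (0.26, 0.13 and 0.16). At 6 hr CDKN1A, MDM2, DDB2, GADD45A, XPC, PHPT1, AEN and BBC3 all passed with the block and not without it (0.57, 0.55, 0.55, 0.66, 0.35, 0.45, 0.40 and 0.52), and at 1 hr none of the 9 passed in either fit (-0.04 to 0.39). Fitting only the groups compared left 1 gene at 2 hr and 0 at 6 hr in limma, where every gene named as passing without the block lost its call (adjusted p from 0.138 to 1), and VWCE missed the threshold without 1 array of 1.5 Gy (adjusted p = 0.111).

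The p53 targets were higher at 1.5 than at 0.30 Gy at 1 hr (median 0.058, adjusted p = 5.19e-07), 2 hr (median 0.14, adjusted p = 2.04e-19) and 6 hr (median 0.30, adjusted p = 6.44e-37). Members past the threshold numbered 0, 2 and 1 in limma, 1, 4 and 11 adjusted over the list alone, and 1, 14 and 21 with the block. With the block and an estimated correlation the 1 hr list did not pass (adjusted p = 0.0914). The B cell markers were lower as a list at 2 hr (adjusted p = 0.0125) and 6 hr (adjusted p = 0.0102), each with adjusted p = 0.999 with an estimated correlation. At 6 hr the heat shock genes (adjusted p = 0.0182, adjusted p = 0.999 with an estimated correlation) and the hypoxia and glycolysis genes (adjusted p = 0.000322, adjusted p = 0.862 with an estimated correlation) were lower as lists. So were the oxidative stress genes (adjusted p = 0.0396, adjusted p = 0.581 with an estimated correlation). In these 4 lists 0 members passed singly in limma or adjusted over the list alone. The oxidative stress list did not pass without shared members (adjusted p = 0.0825). With the block, interferon response genes were lower as a list at 1.5 Gy at 1, 2 and 6 hr (adjusted p = 0.00941, 0.00138 and 0.0113), and not with an estimated correlation as well (adjusted p = 0.462, 0.34 and 0.476). Also with the block, neutrophil markers were lower at 1 and 6 hr (adjusted p = 0.011 and 0.000213) and T cell markers at 1 and 2 hr (adjusted p = 0.00781 and 0.00159). With an estimated correlation as well neither list passed (adjusted p = 0.449 and 0.233, and 0.541 and 0.449). Erythroid markers were higher with the block at 1 hr (adjusted p = 0.00393) and NF-kB and heat shock genes at 2 hr (adjusted p = 0.0434 and 0.00016), none with an estimated correlation as well (adjusted p = 0.444, 0.786 and 0.404). At 6 hr ribosomal protein genes were higher and glucocorticoid response genes lower with the block (adjusted p = 0.00853 and 0.0473), again not with an estimated correlation as well (adjusted p = 0.7 and 0.21). BCL2 family genes were higher at 6 hr with the block (adjusted p = 0.00298), also with an estimated correlation (adjusted p = 0.0137), while without the block and without shared members they did not pass (adjusted p = 0.994).

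**Figure D3:**
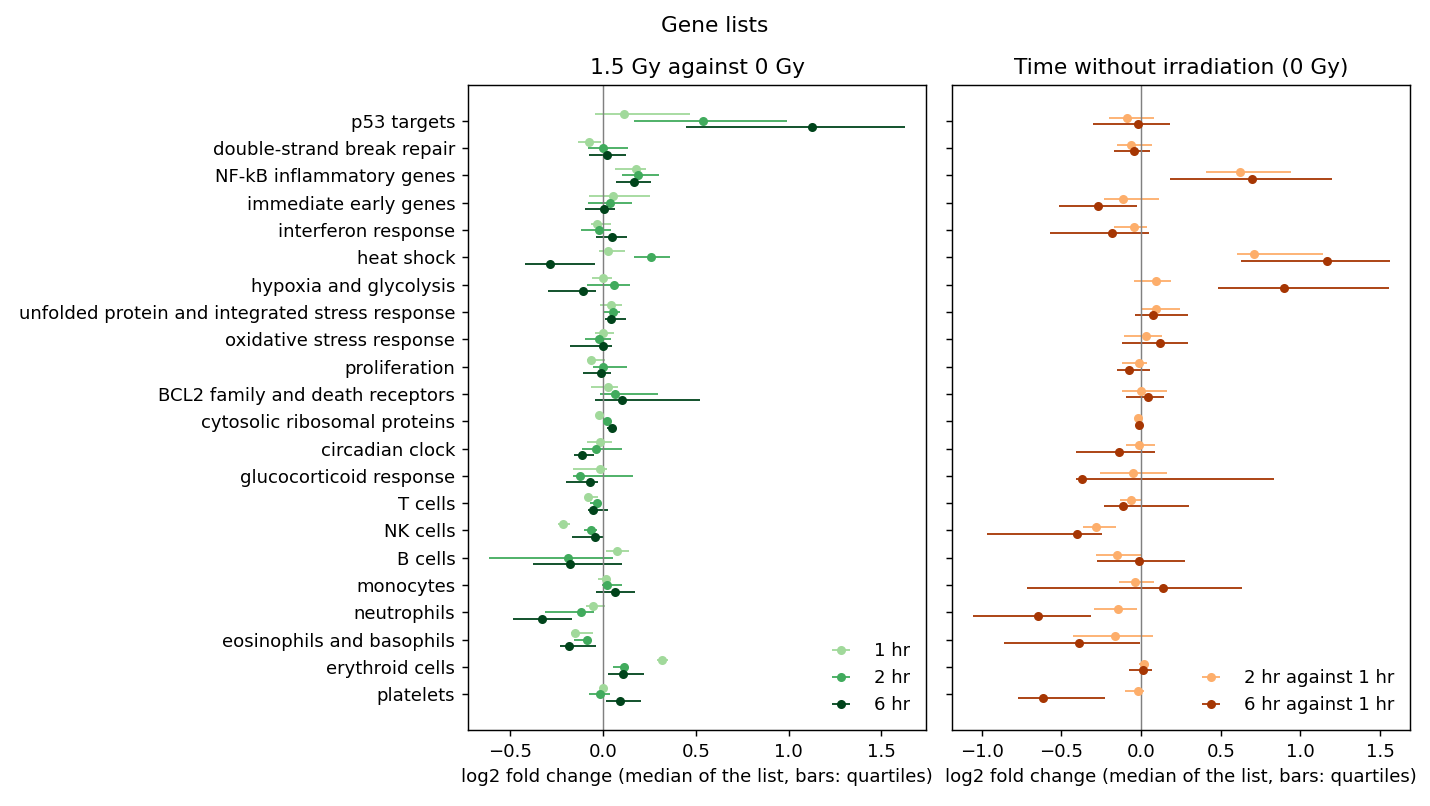
Median log2 difference of each gene list (horizontal axis, bars from the lower to the upper quartile of its genes), for 1.5 Gy against 0 Gy at the 3 times (left) and for 2 and 6 hr against 1 hr at 0 Gy (right). The p53 targets have a median of 1.13 at 6 hr after 1.5 Gy, while the neutrophil markers have a median of -0.33.

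Unirradiated blood was compared over time to give the background against which later dose effects stand. From 1 to 2 hr at 0 Gy the lipid-sensing receptor gene PPARG rose from a mean log2 value of 4.92 to 7.67, by 2.75 ± 0.30 (n = 10 per group, 6.71-fold, adjusted p = 2.4e-11). The monocyte chemokine genes CCL7 and CCL2 rose by 2.53 ± 0.49 and 2.16 ± 0.48, the urokinase gene PLAU by 2.43 ± 0.35 and the cytokine gene IL1A by 2.42 ± 0.63. COXFA4L3, HSPA1B, the chaperone gene HSPH1, the fatty acid receptor gene GPR84 and the myeloid lectin gene CLEC5A rose by 2.47, 2.24, 1.96, 1.94 and 1.74. RELL1, MAK and the calcium channel gene CACNA2D3 fell by 1.10, 1.05 and 1.03. GTF2IRD2, ANKRD44, CFAP45, the peroxisomal transporter gene ABCD2, FOSB, CDADC1 and the NK cell receptor gene CD160 fell by 1.00, 0.97, 0.97, 0.96, 0.93, 0.92 and 0.91. CACNA2D3 just missed the threshold when only the groups compared were fitted (adjusted p = 0.0513).

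By 6 hr at 0 Gy COXFA4L3, a mitochondrial protein gene, had risen from a mean log2 value of 6.82 to 12.92, by 6.11 ± 0.59 (n = 5 and 10, 69.0-fold, adjusted p = 1.06e-14). The osteopontin gene SPP1 rose by 5.83 ± 0.53 (adjusted p = 8.68e-16). FPR3, a receptor of monocytes and macrophages, rose 24.3-fold (adjusted p = 3.25e-17), the fibronectin gene FN1 by 3.79 ± 0.26, and the lipid droplet genes PLIN2 and HILPDA by 3.70 ± 0.24 and 3.61 ± 0.32. The chemokine genes CXCL10, CCL2 and CCL7 rose by 3.55 ± 1.06, 3.49 ± 0.59 and 3.49 ± 0.60, and TMEM51 by 3.46 ± 0.24. LGALS2, a galectin gene, fell by 2.81 ± 0.54 and PROK2 fell by 2.57 ± 0.37. CACNA2D3, CD160, TSPAN2, the cell cycle inhibitor gene CDKN1C, EFHC2, the immediate early gene EGR3, MAK and FAR2 fell by 2.46, 2.18, 2.11, 2.09, 2.09, 2.02, 2.02 and 2.02. CXCL10 missed the threshold without either of 2 arrays of 0 Gy at 6 hr (adjusted p = 0.102 and 0.0839).

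From 1 to 2 hr 1781 genes passed at 0 Gy (764 that rose, 1017 that fell) and 5673 with the block (2174 and 3499), but with arrays centred on their medians 936 rose and 858 fell, so the balance of directions depends on the scaling. From 1 to 6 hr 3798 passed (1473 that rose, 2325 that fell, and 1840 and 1967 with centred arrays) and 4840 with the block, which used numbers 1 to 4 only, 3368 of them shared. The heat shock genes rose from 1 to 2 hr (13 of 17, 15 adjusted over the list alone, median 0.71, adjusted p = 7.52e-15, adjusted p = 0.0893 with an estimated correlation). By 6 hr 14 had risen, and adjusted over the list alone 14 had risen and 1 had fallen (median 1.17, adjusted p = 2.45e-09, adjusted p = 0.388 with an estimated correlation). NF-kB genes rose from 1 to 2 hr (13 of 27, 18 adjusted over the list alone, adjusted p = 9.82e-10, adjusted p = 0.404 with an estimated correlation), among them the inhibitor genes NFKBIE (0.96) and NFKBIA (0.61). By 6 hr 16 NF-kB genes had risen and 2 had fallen, 17 and 3 adjusted over the list alone (adjusted p = 4.77e-05, adjusted p = 0.942 with an estimated correlation). CCL20 was higher by 3.45 and the prostaglandin synthase gene PTGS2 was lower (-1.99). Hypoxia and glycolysis genes had risen by 6 hr (19 of 26, 20 adjusted over the list alone, median 0.90, adjusted p = 1.36e-23, 0.00176 with an estimated correlation), such as LDHA (1.43 ± 0.08), P4HA1 (2.75 ± 0.15) and VEGFA (2.49 ± 0.20). Of the 13 NK cell markers 6 fell by 6 hr, such as PRF1, the perforin gene (-1.08), 6 adjusted over the list alone, and the list fell (adjusted p = 0.0162, adjusted p = 0.999 with an estimated correlation). Of the 15 neutrophil markers 9 fell, such as MME (-1.97), 9 adjusted over the list alone, and the list fell (adjusted p = 0.000674, adjusted p = 0.581 with an estimated correlation). With the block, NK cell (adjusted p = 0.00219) and neutrophil markers (adjusted p = 0.0203) fell as lists from 1 to 2 hr and B cell markers (adjusted p = 0.0313) from 1 to 6 hr. None passed with an estimated correlation as well (adjusted p = 0.61, 0.541 and 0.567).

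**Figure D4:**
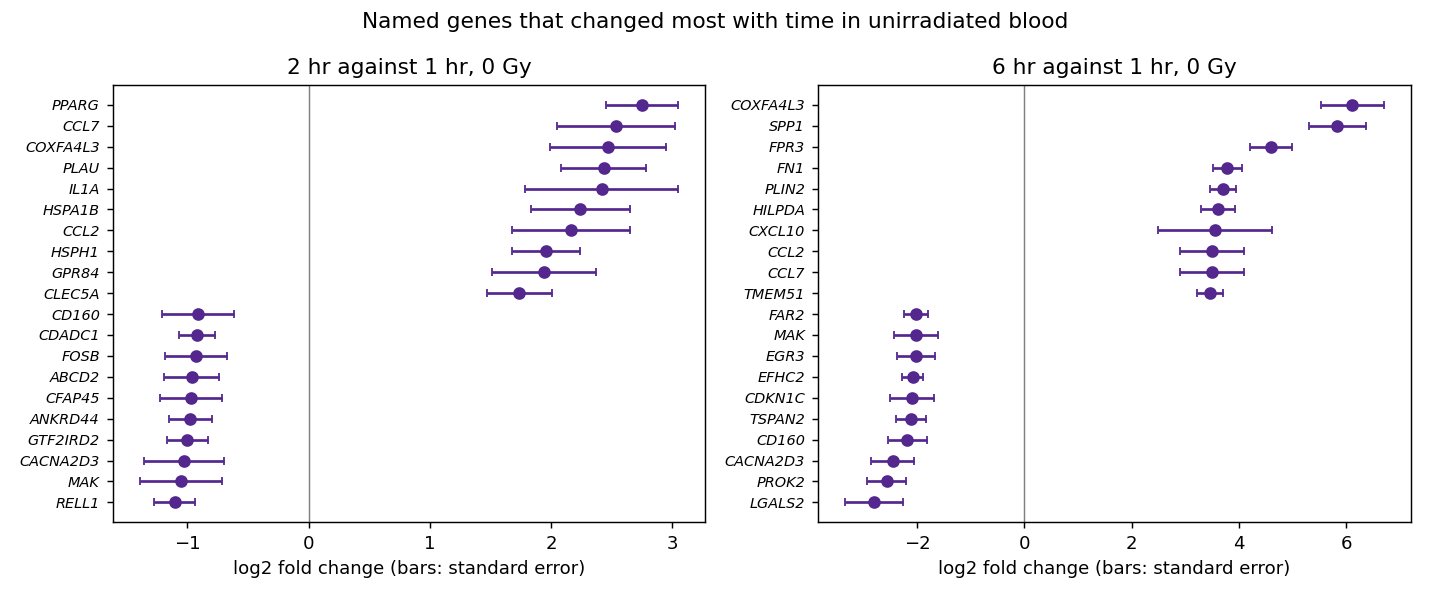
Log2 difference (horizontal axis, bars of 1 SE from limma) of the named genes in unirradiated blood at 2 hr against 1 hr (left) and 6 hr against 1 hr (right), with n = 10 at 1 and 2 hr and 5 at 6 hr. PPARG differs by 2.75 on the left and COXFA4L3 by 6.11 on the right.

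Whether the effect of 1.5 Gy itself changed with time was tested as an interaction. From 1 to 2 hr the effect on MDM2 grew by 1.29 ± 0.16 (adjusted p = 3.6e-08), on LINC00158 by 1.23 ± 0.18 (adjusted p = 2.76e-06) and on EBI3 by 1.04 ± 0.19 (adjusted p = 0.00105). It grew on the lymphocyte transcription factor gene IRF4 by 0.96 ± 0.21 (adjusted p = 0.0176) and on TRIAP1 by 0.95 ± 0.17 (adjusted p = 0.000323). From 1 to 6 hr the effects on TNFSF4, DDB2, PHPT1, ACTA2 and ASCC3 grew by 2.73 ± 0.25, 2.56 ± 0.23, 2.14 ± 0.21, 1.99 ± 0.37 and 1.84 ± 0.18. GNG7 and TBXAS1 moved the other way by -1.62 ± 0.35 (adjusted p = 0.00443) and -0.55 ± 0.14 (adjusted p = 0.0353). The groups had 10 arrays at 1 and 2 hr and 5 at 6 hr.

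The effect of 1.5 Gy differed between 1 and 2 hr for 17 genes, all with a higher effect at 2 hr (0 lower in limma, 652 at an unadjusted p under 0.05), and for 1612 with the block (1243 higher, 369 lower). Between 1 and 6 hr it differed for 56 genes (54 higher, 2 lower) and for 1365 with the block (940 higher, 425 lower). In the fit with the block the effect at 2 hr was lower for the B cell genes TCL1A (-0.92), IGHV5-78 (-0.92), BLNK (-0.87), POU2AF1 (-0.85) and VPREB3 (-0.81) and higher for the B cell gene MS4A1 (0.76, adjusted p = 1.44e-09). The effect at 6 hr was lower for DSP (-1.41), CD69 (-1.27) and TSPAN13 (-1.17). Fitting only the groups compared left 8 genes for 2 hr, without IRF4 (adjusted p = 0.233), and TBXAS1 lost its call for 6 hr there (adjusted p = 0.603) and without any of several single arrays (adjusted p = 0.0676 to 0.293).

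The effect on p53 targets grew from 1 to 2 hr (8 of 38, 19 adjusted over the list alone, median 0.39, adjusted p = 5.75e-32). It also grew to 6 hr (18 of 38, 25 adjusted over the list alone, median 0.84, adjusted p = 2.63e-99), and BAX was at 0.75 and 1.70. BCL2 family genes followed (adjusted p = 0.00348 and 5.96e-05, and 0.658 and 0.916 without shared members), with 1 and 2 members past the threshold and 3 and 5 adjusted over the list alone. The effect on heat shock genes was higher at 2 hr than at 1 hr (adjusted p = 0.0312, adjusted p = 0.999 with an estimated correlation), with HSPH1 at 0.45. It was lower at 6 hr (adjusted p = 0.000723, adjusted p = 0.994 with an estimated correlation), with HSPH1 at -0.64. The effect on B cell markers was lower at 2 hr (adjusted p = 0.00498) and 6 hr (adjusted p = 0.0162), each with adjusted p = 0.999 with an estimated correlation and 2 members adjusted over the list alone. At 6 hr it was also lower for immediate early genes (adjusted p = 0.00211, adjusted p = 0.942 with an estimated correlation, 1 member adjusted over the list alone). The same held for neutrophil markers (adjusted p = 0.00145, adjusted p = 0.626 with an estimated correlation) and hypoxia genes (adjusted p = 0.000702, adjusted p = 0.934 with an estimated correlation). In the heat shock, B cell, immediate early, neutrophil and hypoxia lists 0 members passed singly in limma, nor did any heat shock, neutrophil or hypoxia gene adjusted over the list alone. With the block MYC was at -1.14 and JUN at -1.09 for 6 hr. With the block, the effect at 2 hr was lower for immediate early genes (adjusted p = 0.0132) and neutrophil markers (adjusted p = 3.46e-05), and not with an estimated correlation as well (adjusted p = 0.509 and 0.173). The effect on ribosomal protein genes was higher with the block at 2 hr (adjusted p = 0.0275) and 6 hr (adjusted p = 0.000164), again not with an estimated correlation as well (adjusted p = 0.786 and 0.509).

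Some lists passed in no comparison without the block. For double-strand break repair genes the smallest adjusted p was 0.0556 (1.5 Gy at 1 hr, median -0.077, 0.0554 with the block), where DCLRE1C, the nuclease Artemis, was at -0.20 (adjusted p = 0.000165 with the block). Proliferation genes (adjusted p = 0.222) and platelet markers (adjusted p = 0.106) did not pass with the block either. Smallest values without the block were 0.649 for the interferon response, 0.0803 for the stress response, 0.202 for ribosomal protein genes, 0.102 for the circadian clock, 0.248 for the glucocorticoid response, 0.316 for T cells, 0.139 for monocytes and 0.399 for eosinophils and basophils. The ribosomal protein genes fell as a list with the block at 1 hr after 0.30 Gy (adjusted p = 0.031), and not with an estimated correlation as well (adjusted p = 0.786).

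The 3' minus 5' signal of the GAPDH and ACTB control probe sets, a sign of RNA integrity, had group means from 0.469 to 0.594. Each dose was compared with 0 Gy at its time and 2 and 6 hr with 1 hr at 0 Gy, and no 2-sided permutation test, exact at 6 hr, passed (p from 0.418 to 0.976, adjusted p = 0.976 in all 11). In pairs, 0.15 Gy at 1 hr was lower than 0 Gy by -0.053 (exact p = 0.0293, adjusted p = 0.322).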

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

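The tests of B cell share, of stray hybridisation, of neutrophil share and of standing time were chosen only after the results were seen, as was the comparison of the overlap at 1 hr with simulated data.

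Of 156 checks for a single array standing apart (13 measures in 12 groups), 18 did so. Independent checks would do so by chance about 1 time in 20, but these are not independent, because arrays with the same replicate number are paired and the measures share arrays, so the 18 do not count as separate events. The array with the lowest mean correlation had 0.976 (next 0.981) at 0 Gy 1 hr, 0.978 (next 0.984) at 0 Gy 2 hr, 0.974 (next 0.982) at 0.15 Gy 1 hr, 0.978 (next 0.985) at 0.15 Gy 2 hr, 0.976 (next 0.982) at 0.30 Gy 1 hr, 0.979 (next 0.984) at 0.30 Gy 2 hr, 0.965 (next 0.982) at 1.5 Gy 1 hr and 0.979 (next 0.983) at 1.5 Gy 2 hr. The lowest array median was 6.051 (next 6.068) at 0 Gy 6 hr, 6.024 (next 6.066) at 0.15 Gy 1 hr and 5.899 (next 6.056) at 1.5 Gy 1 hr. One array of 0 Gy at 1 hr had a 3' minus 5' signal of 1.161 (next 0.737). CDKN1A was highest at 10.224 (next 9.574) in an array of 0 Gy at 1 hr and lowest at 11.015 (next 11.643) in one of 1.5 Gy at 6 hr. AEN was lowest at 7.249 (next 7.889) at 0.15 Gy 1 hr and at 7.451 (next 8.070) at 0.30 Gy 1 hr. BBC3 was highest at 9.087 (next 8.493) at 0 Gy 6 hr and lowest at 8.065 (next 8.815) at 1.5 Gy 1 hr.

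The effect of 1.5 Gy differed between 1 and 2 hr for 17 genes, with MDM2 at 1.286, LINC00158 at 1.227, EBI3 at 1.043, IRF4 at 0.956 and TRIAP1 at 0.949. Between 1 and 6 hr it differed for 56 genes, with TNFSF4 at 2.727, DDB2 at 2.560, PHPT1 at 2.135, ACTA2 at 1.989, ASCC3 at 1.840, GNG7 at -1.615 and TBXAS1 at -0.546.

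In the fit with the block, 284 genes fell at 1 hr after both 0.15 Gy and 1.5 Gy by similar amounts (medians -0.174 and -0.187). They were picked for passing at both doses against the same 0 Gy arrays. That choice draws the 2 medians together, so their likeness alone does not show that the fall was the same at both doses. Independent lists of 309 and 1172 genes would share 25.8. In simulated data with shared controls and no effect, 2 lists of these sizes shared at most 159. The simulated genes varied independently of each other. In the real arrays, exchanging the groups within replicate numbers called up to 408 and 1222 genes at these doses, with a median of 0 at each. Exchanges of few pairs keep much of the real difference, so the highest counts are not free of it. Because its genes were independent, the simulation cannot bound the overlap that shared controls give here. A different lysis time could have lowered the 284 genes. In the 0.30 Gy arrays 54.9% of them changed in the commoner direction from 1 to 2 hr (52.537% of all genes). But those arrays showed a fall against 0 Gy as well (median -0.175 at 1 hr, against the same 0 Gy arrays, and -0.109 at 2 hr). Their change with time starts from tubes that may share the cause, so a different lysis time stays undecided. Chance values of the shared 0 Gy arrays were checked in parts that share no array. The 300 genes picked at 0.15 Gy in numbers 1 to 5 had a median of -0.17 at 1.5 Gy in numbers 6 to 10. Sharing 0 Gy arrays alone does not give that median. But it was held against a fixed bound and not against exchanged groups. Genes that vary together can move by chance in both parts, so chance is not excluded. The check was not repeated without the arrays of lowest correlation. RNA integrity stays undecided: the median correlation with the 3' minus 5' signal was 0.179, which met the bound of 0.2 written beforehand, but quartiles of -0.213 and 0.509 led to a stricter reading after the value was seen. Another handling of the 0 Gy tubes, or a response that does not grow with dose, may remain.

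B cell genes moved apart at 2 hr after 1.5 Gy in the fit with the block, with MS4A1 (0.841) and BLK (0.253) higher and TCL1A (-1.204), BLNK (-0.882), VPREB3 (-0.705), CD79B (-0.695), CD72 (-0.370), FCRLA (-0.324) and FCRL1 (-0.189) lower. Another share of B cells alone could move all markers one way only, but 2 went up and 7 down, so the rarer direction held 2, which leaves open that a share changed in part. Stray hybridisation of single probe sets is unlikely for the 6 markers with another probe set above the filter, taken as a set, since 83.3% of them had it moving the same way. But the other probe sets of CD79B (-0.119 and -0.148, adjusted p = 0.318 and 0.0785) and of FCRL1 (-0.186, 0.016 and -0.129, adjusted p = 0.0748, 0.917 and 0.313) did not pass and do not support those 2 calls. BLNK, VPREB3 and CD72 had no other probe set above the filter, so the check does not cover them. The rule on other probe sets was made stricter after its first value was seen, by asking for at least 2 markers with another probe set past the threshold and none opposite, and 4 and 0 were found. A response of B cells themselves may remain and was not tested.

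The neutrophil markers fell at 6 hr after 1.5 Gy (median -0.327). As a list they did not pass with an estimated correlation, and no member passed singly without the block. A lower share of neutrophils alone could raise the markers of all other leukocytes. The T cell markers (median -0.051), NK cell markers (-0.041) and monocyte markers (0.063) did not clearly rise, which speaks against that. The rule was met only through the eosinophil and basophil markers (median -0.182). Their share could fall together with that of neutrophils, so the rule does not exclude a lower share of both. Longer standing of irradiated tubes could lower the neutrophil markers, which also fell with time at 0 Gy. It is unlikely, since heat shock and hypoxia genes, which rise with time, had medians no higher than -0.109 after 1.5 Gy. Neither of those 2 lists passed after 1.5 Gy with an estimated correlation, which limits this argument. Chance values of the 5 control arrays stay undecided: the highest of 4 medians in parts of the arrays was -0.057, which met the bound of -0.05 written beforehand, but its upper quartile of 0.039 led to a stricter reading after the value was seen. The parts were not all separate, since the 0.15 and 1.5 Gy parts of the same replicate numbers used the same 0 Gy arrays. Lower transcript levels within neutrophils may remain and were not tested.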

How the results depend on the processing

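The fits without the arrays of lowest correlation and the list test with both the block and an estimated correlation were chosen only after the results were seen.

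Of 282 named gene and comparison pairs, 163 passed, and all 163 kept their direction and call with the block, which passed 94 more. Part of the 94 were named because they passed with the block, to fill unfilled places. Their passing there was fixed by the rule for named genes. Except for 6 against 1 hr, the block leaves each difference unchanged and alters only its SE, so the kept directions there were fixed by the design. Every probe set on its own and the trended and robust prior lost 0 of the 163 calls and the stricter filter 0 of the 158 it kept. No filter lost 4, centring 1 and fitting only the groups compared 37. Leaving out single 6 hr arrays lost 19 of 580 calls, and the cause was not tested. BBC3 (0.53, adjusted p = 0.0243) at 1 hr after 1.5 Gy and XPC (0.49, adjusted p = 0.0281) at 2 hr after 0.30 Gy passed without the arrays of lowest correlation, where C7orf25 did not (-0.48, adjusted p = 0.198). XPC at 1 hr after 1.5 Gy, -0.003 without passing, was 0.014 with centred arrays, 0.017 without the arrays of lowest correlation and 0.017 with the block as well, and PHPT1, at -0.002, was 0.015, 0.006 and 0.006. Without single arrays the 6 hr counts were 15 to 25, 28 to 34 and 64 to 87 for the 3 doses, 3 to 5 for 1.5 against 0.30 Gy, 3206 to 3498 for 6 against 1 hr and 41 to 55 for the interaction.

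With the replicate block the counts at 0.15, 0.30 and 1.5 Gy were 413, 1006 and 1701 at 1 hr, 614, 1701 and 3301 at 2 hr, and 159, 1109 and 1992 at 6 hr. Between 1.5 and 0.30 Gy they were 5, 253 and 182, for 2 against 1 hr 5673, and for the interactions 1612 and 1365. With the block and without the arrays of lowest correlation they were 386, 1013 and 1337 at 1 hr, 584, 1645 and 3219 at 2 hr, 7 and 274 between 1.5 and 0.30 Gy at 1 and 2 hr, 5430 for 2 against 1 hr, and 1149 and 1178 for the interactions. Every probe set on its own gave 5 (0.30 Gy) and 29 (1.5 Gy) at 1 hr, 40, 58 and 306 at 2 hr, 49, 80 and 203 at 6 hr, 27 and 7 between 1.5 and 0.30 Gy at 2 and 6 hr, 4046 and 9257 for the times, and 53 and 140 for the interactions. Fitting only the groups compared gave 4 at 1 hr and 89 at 2 hr after 1.5 Gy, 10 at 6 hr after 0.15 Gy, 1 and 0 between 1.5 and 0.30 Gy at 2 and 6 hr, and 8 for the 2 hr interaction.

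Of 352 list tests 62 passed, against 23 with an estimated correlation, 106 with the block and 24 with both. The paired 3' minus 5' difference of -0.053 at 1 hr after 0.15 Gy had an exact p of 0.0293, adjusted p = 0.322.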

Other observations

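In this part no test was chosen only after the result was seen.

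In unirradiated blood 4 of 14 platelet markers fell and 1 rose from 1 to 6 hr in limma, and the list did not pass (adjusted p = 0.106). The platelet receptor gene CLEC1B fell by 1.02 ± 0.26 (n = 5 and 10, adjusted p = 0.00156), the platelet tubulin gene TUBB1 by 1.37 ± 0.36 (adjusted p = 0.00188), SPARC by 1.10 ± 0.34 (adjusted p = 0.00938) and GP1BA by 0.63 ± 0.24 (adjusted p = 0.0375, adjusted p = 0.13 with the block). At 6 hr after 0.30 Gy the monocyte scavenger receptor gene CD163 rose by 0.53 in the fit with the block (n = 5 per group, adjusted p = 0.00138) and CD14 by 0.22 (adjusted p = 0.00588). In that fit 4 of 13 monocyte markers rose, and the list rose (adjusted p = 0.00304, adjusted p = 0.43 with an estimated correlation as well).

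Splitting the same arrays in 100 ways, the real one included, asked whether chance can be excluded. At 1 and 2 hr fewer than 5 in 100 splits called as many genes as the real one: 4 for 0.15 Gy (3 genes, highest other 32), 1 for 0.30 Gy (3, highest other 1) and 1 for 1.5 Gy (17, highest other 3) at 1 hr, and 1 (15, highest other 5), 2 (20, highest other 24) and 2 (134, highest other 141) at 2 hr. The same held for 1.5 against 0.30 Gy at 2 hr (2 splits, 16 genes, highest other 32), 2 against 1 hr (1, 1781 genes, highest other 185) and 6 against 1 hr (1, 3798 genes, highest other 2555). For the interactions the arrays were not split. The residuals from added effects of dose and time were exchanged between times within a dose, without regard to pairs. Of 100 such arrangements, the real one included, 1 and 2 called as many genes (17 and 56 genes, highest other 1 and 419). At 6 hr 9, 8 and 7 splits did so for 0.15, 0.30 and 1.5 Gy (21, 33 and 78 genes, highest other 481, 695 and 835), and 18 for 1.5 against 0.30 Gy (4 genes, highest other 319), so these splits do not exclude chance. For 1.5 against 0.30 Gy at 1 hr the real count was 0, which every one of the 100 splits reaches (highest other 1117), so that number decides nothing. Counts several times the real one point to a structure of the samples. Among splits that part the pairs as the real one does, none of 99 others at 1 and 2 hr called as many genes for any dose against 0 Gy (highest others 2, 2 and 6 at 1 hr and 8, 13 and 40 at 2 hr). At 6 hr the 16 such splits are too few for a share under 0.05, but their highest others were 8, 9 and 22 instead of 481, 695 and 835, so the high counts there came with splits that leave the pairs uneven. For 2 against 1 hr the splits that part the pairs reached 795, above the 185 of the other splits.

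With the block, 1 of 100 splits within replicate numbers, the real one, called as many genes at 1 and 2 hr, with the highest others at 408, 489 and 1222 at 1 hr and 108, 1227 and 2296 at 2 hr against the real 413, 1006, 1701, 614, 1701 and 3301. At 6 hr the splits are again too few, and the real counts of 159, 1109 and 1992 stood against highest others of 132, 316 and 762. The median of the other splits was 0 for each dose at 1 and 2 hr and 1 for each dose at 6 hr. Splits that exchange few pairs keep much of the real difference, so the highest counts are not free of it.

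A hypothesis is that 3 ERCC probe sets (means 10.645, 8.142 and 7.415) could be bright because bacterial control transcripts hybridise to them. Their correlations with the mean of 24 bacterial control probe sets over the 100 arrays were 0.999, 0.995 and 0.995 (permutation p = 1e-05 each, the smallest possible), and the lowest, 0.995, is consistent with it.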
